A study of Mus musculus with 84 samples.

How the data were processed

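The series holds RNA-seq of MMC9s, IL-9-producing mucosal mast cells sorted from the small intestine of BALB/c mice with ovalbumin-induced food allergy. The bulk part has 3 libraries, 1 per genotype (WT, IL4RaY709F and IL4Ra-/-). Per the labels, bone marrow progenitors of each genotype were transferred into ovalbumin-sensitized WT mice, which then received 7 oral ovalbumin challenges at 3 per week, and each RNA sample was pooled from 12 to 20 biological replicates. The single-cell part has 81 WT MMC9s from an ovalbumin and alum model, sorted as Lin- IL-4GFP high IL-17RB2- c-Kit+ ST2+ cells with low β7-integrin. The labels name no animal for these cells, so they were treated as 1 sample. The gate used for the bulk sort is not given in the sources used here.

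Per the labels, RNA was isolated with a column kit and libraries were made with standard Illumina chemistry. Per the submitters' processing notes, reads were aligned with HISAT and assigned to genes with featureCounts of Subread 2.0.0. The authors deposited whole-number read counts per gene, with no normalization, for the bulk libraries and for the cells alike. RPKM values, which the design text mentions for the cells, were not used here. The processing notes name the builds GRCm38 and mm9 without their roles. The coordinates in the deposited count tables were therefore compared with the GRCm38 annotation of GENCODE M21: of 55471 gene IDs, 55144 were found there, and 54851 of those (99.5%) had the same chromosome, start and end. All coordinates given are GRCm38. The strand setting, the handling of reads that map to several places and any molecular identifiers are not given in the sources used here. Reads from a gene and an overlapping or antisense gene could not be told apart, and the split of reads among near-identical genes (the Serpina3 cluster, Mcpt1, Mcpt2 and Mcpt4, the tryptases, immunoglobulin segments and MHC class II genes) is uncertain. Reads are not independent molecules, so every interval and floor covers counting error only.

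There was 1 library per genotype, so no model of the spread between animals could be fitted and no p-value was computed. For each gene, reads scaled to a common total (CPM) were scaled with the trimmed mean of M-values (TMM, edgeR 4.0.16) over the 3 bulk libraries. The log2 ratio of 2 libraries carries an exact conditional binomial (Clopper-Pearson) 95% interval. A gene passed the size rule when its larger library had at least 50 reads, its ratio was at least 2-fold, and the interval excluded a ratio of 1. A gene at 0 reads was set to a floor of 3 reads in ratios, which are then bounds, and a gene with 1 to 3 reads has its ratio with the interval. For each of 33 gene lists (19 of pathways and 14 of cell types), the median log2 ratio of members with at least 20 reads summed over the 3 libraries was placed among the medians of 10000 random lists of the same size matched on mean expression. A list was called apart below the 2.5th or above the 97.5th percentile, as a description of these libraries. Eosinophil, neutrophil and erythroid lists had too few measured members for a median. For each other cell type the list genes detected in under 5% of the WT single cells, called rare in MMC9s, were also summed per library, whatever their level. Genes ordered with receptor activity had WT between the mutants and passed the size rule between the mutants.

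Both comparisons with WT share the WT library. Overlaps of the gene sets are given beside the overlap of independent lists and the mean of 100 simulated pairs of unchanged libraries with counting noise only. After the data were seen, 100 simulations each were added with a lognormal spread between libraries, of 0.138 (natural log SD, set on the spread of the ratios to WT among genes with 200 to 1000 reads) or 0.3, and 100 shuffles of the IL4Ra-/- to WT ratios among genes of like level, which make the effects of the mutants independent. The correlation of the 2 fold changes, over genes with at least 50 reads in each library, is given with its covariance, the simulated values and a repeat with WT reads thinned into 2 separate parts. With 1 WT library, the controls could not be split into sets of 2 libraries each.

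Single cells were kept with at least 500 detected genes and 10000 gene reads, which left 80 of 81. A gene was called detected in a cell at 10 reads or more, and shares of cells have exact (Clopper-Pearson) 95% intervals. No doublet caller was run on the individually sorted cells, and no clusters were formed. A count of 0 of 80 cells has an exact upper limit of 4.51%. The reads of the kept cells were summed and compared with WT bulk over genes with at least 50 reads in either, on the log2(CPM + 1) scale.

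Genes named in the text followed a rule fixed before the data were examined, as were the lists, the size rule and the alternative settings. They are 12 genes always named (Il4ra, Stat6, Batf, Irf4, Il9, Il13, Il4, Il6, Kit, Mcpt1, Mcpt2 and Cpa3), the 8 highest and 8 lowest genes past the size rule with at least 200 reads against WT and between the mutants, and 2 to 4 members per list with the largest ratio and at least 50 reads. For single cells the rule added the 10 genes with the highest mean CPM and up to 4 members per list with the highest share. Gene models without a family symbol were left out. Any other named gene is marked as chosen after its values were seen.

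The other settings chosen in advance were scaling by total reads, DESeq2 1.42.0 size factors or upper quartiles, other read minimums and folds, a ratio interval that excludes 2, removal of mitochondrial, ribosomal protein, hemoglobin and immunoglobulin genes, other member minimums and means for lists, and other detection limits, cell filters and thinning for cells. Further settings were added after the data were seen: counting only genes detected in 2 or more WT cells, leaving out cells with over 10% immunoglobulin reads, and matching random lists on exon length (5 bins within 10 bins of expression). The size rule and the list percentiles were first tested on simulated counts drawn at the real levels and library sizes. Without extra noise, 52% of genes raised 2-fold and 100% of genes raised 3-fold passed in the simulated IL4RaY709F comparison over 6043 genes, and 1 of 5846 unchanged genes passed. In the simulated IL4Ra-/- comparison over 5944 genes these values were 44%, 100% and 4 of 5749. With an added spread of 0.3 (natural log SD), 794 of 6016 unchanged genes passed for IL4RaY709F and 821 of 5921 for IL4Ra-/-. Without extra noise, 2 and 3 of 20 unshifted lists were called apart in the 2 simulated comparisons. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and under R 4.3.3.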

Results

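MMC9s are a rare mast cell population of the intestinal mucosa that releases large amounts of IL-9 after repeated oral exposure to a food allergen. Bulk RNA-seq was done on small-intestinal MMC9s of 3 genotypes, with 1 pooled library each. The genotypes were WT, IL4RaY709F, a gain-of-function form of the IL-4 receptor alpha chain that lacks an inhibitory tyrosine, and IL4Ra-/-, its loss of function. The libraries held 2299793 (WT), 2521791 (IL4RaY709F) and 2330628 (IL4Ra-/-) reads in genes, and 3 reads corresponded to between 1.18 and 1.31 CPM. There were no replicate libraries, so every difference is between libraries and has no replicate check. For genes with 200 to 1000 reads the log2 ratios against WT had a robust SD of 0.28 in IL4RaY709F and 0.33 in IL4Ra-/-, above the median counting error of 0.12 in each. A second data set held 81 WT MMC9s sequenced singly, with 163596 to 2210211 gene reads in each of the 80 cells kept (median 1209300).

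The first comparisons asked how the IL-4 receptor shapes gene expression in MMC9s, beginning with the receptor and the transcription factor BATF that the study names. Il4ra (ENSMUSG00000030748, GRCm38 chromosome 7, 125552120 to 125579474, plus strand), the gene altered in both mutants, stood at 353 CPM in WT, 787 CPM in IL4RaY709F and 138 CPM in IL4Ra-/-. It was 2.23-fold higher in IL4RaY709F (95% counting interval 2.05 to 2.43) and 2.56-fold lower in IL4Ra-/- (2.26 to 2.91), so 39.03% of the WT level was left in the loss-of-function library. The lower level goes in the direction of that library's label. The counts are per gene and the deleted part of the allele is not given in the sources used here, so the reads left could not be placed inside or outside it, and a point mutation leaves no mark in gene counts. Batf (ENSMUSG00000034266, chromosome 12, 85686669 to 85709087), an AP-1 family factor, was 3.03-fold higher in IL4RaY709F (2.68 to 3.43) and 2.92-fold lower in IL4Ra-/- (2.38 to 3.60). Irf4 (ENSMUSG00000021356, chromosome 13, 30749226 to 30766976), a DNA-binding partner of BATF, was 3.93-fold higher in IL4RaY709F (3.38 to 4.58) and had a log2 ratio of -0.52 in IL4Ra-/- (-0.82 to -0.22), which did not pass the size rule. Stat6, the signal transducer of the receptor, did not pass in either mutant (log2 ratios -0.17 and -0.41).

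**Figure D1:**
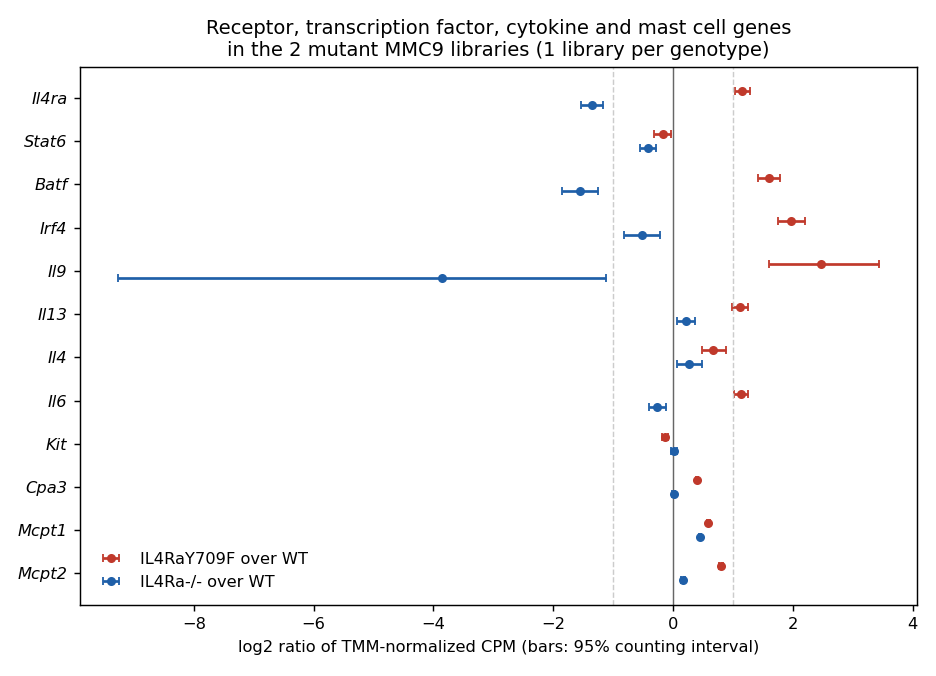
Log2 ratio of normalized CPM against WT (x axis) for the 12 genes fixed in advance, in IL4RaY709F (red) and IL4Ra-/- (blue); points are single libraries, bars are 95% counting intervals and dashed lines mark a 2-fold ratio. Il4ra and Batf lie past 2-fold on opposite sides in the 2 mutants, while Il9, with 1 read in IL4Ra-/-, has the widest interval there (-9.26 to -1.12).

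In IL4RaY709F MMC9s, effector cytokine and granule protease transcripts were higher than in WT, together with Batf, Irf4, Socs1 and Socs3. Il9 (ENSMUSG00000021538, chromosome 13, 56479277 to 56482246), the cytokine that defines MMC9s, rose 5.52-fold (3.03 to 10.9, from 13 to 73 reads). Among the WT single cells, 1 cell held 1137 of the 1139 Il9 reads. The interval does not cover how many such cells a pool held. Il13, a mucosal type 2 cytokine, rose 2.18-fold (1.98 to 2.39) and the inflammatory cytokine Il6 rose 2.20-fold (2.02 to 2.39). The chymase gene Cma1 rose 3.19-fold (3.06 to 3.32) and the cytotoxic protease gene Gzmb 2.95-fold (2.86 to 3.05). Transcripts of macrophages and plasma cells were lower as lists in the same library. The proliferation list was lower too (median log2 ratio -0.35), with no member past the size rule and no call among members of at least 100 reads (-0.15, percentile 4.52).

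The size rule was passed by 100 genes higher and 46 lower of 5964 genes with 50 reads or more. Scaling by total reads moves every ratio of IL4RaY709F to WT by -0.11 log2 and gave 71 higher and 69 lower. Immunoglobulin genes made up 17 of the 46 lower genes and 1 of the 100 higher ones. Among genes detected in at least 2 WT single cells, a set chosen after the data were seen, 93 were higher and 31 lower.

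Of 12 measured type 2 and other effector cytokines, 4 rose and none fell past the rule, with a median log2 ratio of 0.72 (100th percentile of matched random lists). Besides Il9, Il13 and Il6, the fourth was Il10, an immunoregulatory cytokine (log2 2.33, 1.68 to 3.05). Il4 reached a log2 ratio of 0.67 (0.48 to 0.88). Of 13 granule proteases, 3 rose (median 0.63, 100th percentile). These were Cma1, Gzmb and Prss34, a tryptase-family protease also made by basophils (log2 1.37). Tpsb2, a mast cell tryptase, had a log2 ratio of 0.96, Mcpt2 0.80, Mcpt1 0.59 and Cpa3, the mast cell carboxypeptidase, 0.40, all short of 2-fold. The list of mast cell markers lay at 0.41 (100th percentile), with Cma1 as its 1 member past the rule, while Kit, the stem cell factor receptor, was at -0.13. Of 25 mast cell surface receptors 2 rose (median 0.21, percentile 98.6), the adenosine receptor Adora3 (log2 1.12) and the inhibitory receptor Cd200r1 (1.28). Xylt1, which starts the sugar chains of granule proteoglycans, rose by a log2 ratio of 1.53, alone among 19 granule content genes (median 0.11, percentile 85.5).

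Within the list of IL-4 receptor signalling and BATF, 6 of 22 measured genes rose and none fell (median 0.16, percentile 96.2, not apart). Among them were Il4ra, Irf4, Batf and the feedback inhibitors Socs1 (log2 1.43) and Socs3 (1.18). The list came to stand apart with other read minimums for members and with the mean of members. The IL-4 and STAT6 induced list had 2 risers of 12 measured, Il4ra and Socs1 (median 0.11, percentile 77.2), and Cish, another feedback inhibitor, stood at 0.66 and did not pass. Pim2, a survival kinase, rose with a log2 ratio of 1.93 as the 1 member past the rule among 21 apoptosis regulators, whose median of 0.11 turned to -0.00031 with total-read scaling. Nfil3, a basic leucine zipper factor, rose (1.23) as the 1 member of 27 mast cell transcription factors (median -0.04, percentile 17.6). Ccl7, a chemoattractant for monocytes, rose (1.59) as the 1 member of 11 measured chemokines, whose median of 0.04 turned to -0.06 with total-read scaling.

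The 8 highest genes of the IL4RaY709F library with 200 reads or more were Itpripl2 (log2 2.83), H19 (2.23), Serpina3g (2.12), mt-Rnr1 (2.08), Serpina3f (2.07), Irf4, Pim2 and Cma1. H19 is an imprinted noncoding RNA, mt-Rnr1 the small mitochondrial ribosomal RNA, and Serpina3f and Serpina3g are inhibitors of serine proteases. The 8 lowest were the immunoglobulin genes Iglc1 (-2.70), Iglv1 (-1.95), Igha (-1.20), Jchain (-1.04) and Igkc (-1.03), with Rab11fip4 (-1.20), the kinase gene Prkd2 (-1.13) and Meis1 (-1.05), a homeobox factor of early blood progenitors.

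Lists of metabolism stood apart in IL4RaY709F with no single member past the rule. Glycolysis genes had a median log2 ratio of 0.37 (percentile 99.99, 16 of 19 members above 0), as in Slc2a1, a glucose transporter (0.81), and Tpi1 (0.68). Oxidative phosphorylation genes had a median of 0.23 (percentile 99.9, 28 of 32 above 0), as in Ndufb5 (0.97) and Uqcrh (0.60). Across 5794 protein-coding genes the log2 ratio of IL4RaY709F to WT had a Spearman rho of -0.24 with exon length, so shorter genes lay higher, and both lists were still apart among random lists matched on exon length as well (percentiles 100 and 98.2). In IL4Ra-/- this rho was 0.16 over 6033 genes. Of the 33 proliferation genes 26 lay below 0 (percentile 0.015), with Mki67 at -0.98 and Top2a at -0.56. The 7 above 0 included Pcna (0.44, 0.23 to 0.66) and Nusap1 (0.43, -0.16 to 1.03).

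Some marker lists of other cell types stood apart in the IL4RaY709F library, and sums over their genes rare in MMC9s did not always go with them. The macrophage or monocyte list lay at -0.97 (percentile 0, 11 of 14 below 0), with lysozyme Lyz2 as its 1 member past the rule (-1.39), and its rare genes summed to 0.538 of WT (0.446 to 0.647). The B cell or plasma cell list lay at -0.39 (percentile 1.10), with 3 of 11 past the rule, Igha, Jchain and Igkc, while its 7 rare genes summed to 0.812 of WT (0.514 to 1.28). Basophil markers, several of them shared with mast cells, such as Fcer1a and Ms4a2, lay at 0.36 (percentile 99.8), with Prss34 as the 1 of 11 measured members past the rule, and the 2 rare ones summed to 1.01 of WT (0.780 to 1.30). The 4 measured ILC2 markers lay at 0.68 (percentile 99.6), where Il2ra rose (1.59), and the 8 rare genes of the 12 on the list summed to 0.983 of WT (0.492 to 1.96, 19 reads in each library). Medians not apart from matched lists were found for dendritic cell (-0.24), epithelial (-0.03), T cell (-0.83), stromal or endothelial (-0.03) and progenitor markers (-0.11). The 12 rare stromal or endothelial genes, most of them below the read minimum of the list, summed to 0.520 of WT (0.314 to 0.845, from 51 to 27 reads). Cytotoxic lymphocyte markers (0.05), Fc epsilon receptor signalling (0.02), immediate early and NF-kB genes (0.06) and cell stress genes (0.09) were not apart either, and each of these 4 medians was negative with total-read scaling; Gzma, a cytotoxic granule protease, rose 55.03-fold with a wide interval (9.48 to 2212, from 1 to 56 reads). The same held without a change of sign for eicosanoid synthesis (-0.02), interferon response (0.11), the unfolded protein response (0.15) and housekeeping genes (0.16).

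In IL4Ra-/- MMC9s, Batf, Nfil3 and the Socs genes were lower than in WT, Il9 had 1 read, and transcripts typical of macrophages, antigen-presenting, epithelial and plasma cells and of dividing cells were higher. Il9 was 14.5-fold lower with a wide counting interval (2.17 to 615) and too few reads for the size rule. Nfil3 fell 4.15-fold (3.04 to 5.75), Socs1 3.99-fold (2.51 to 6.56) and Socs3 3.68-fold (2.88 to 4.75). No mast cell marker passed the rule, with Kit at a log2 ratio of 0.02, Cpa3 at 0.01, Mcpt1 at 0.45, Hdc at -0.60 and Cma1 at -0.61, and 9 of the 14 lay below 0. The median of these 14 markers was -0.11, at percentile 90.8 of matched lists and so not apart. Mcpt2 was at 0.16. Il4 (0.27), Il13 (0.22) and Il6 (-0.26) did not pass the rule.

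The size rule was passed by 152 genes higher and 81 lower of 6246. Scaling by total reads moves every ratio of IL4Ra-/- to WT by 0.13 log2 and gave 207 higher and 45 lower. Of the 152 higher genes 49 were immunoglobulin genes, and 47 had no WT single cell with 10 reads. Among genes detected in at least 2 WT cells, 87 were higher and 72 lower.

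Of 22 measured genes of IL-4 receptor signalling and BATF, 5 fell and none rose, with 21 below 0 and a median of -0.52 (percentile 0). They included Socs1, Socs3, Batf and Il4ra. Of 31 Fc epsilon receptor signalling genes none passed the rule alone, and 26 lay below 0 (median -0.30, percentile 1.80), among them the kinase Fyn (-0.84) and the adaptors Lat (-0.57) and Lat2 (-0.53). Granule proteases were not apart (median -0.10, percentile 65.4), with a sign that turned to 0.03 under total-read scaling; Prss34 fell (-1.81), and Tpsb2 (-0.75) and Cma1 (-0.61) did not pass. Among granule content genes Ext1, a heparan sulfate polymerase, fell (-1.002), at the edge of the rule. The shifts of 0.13 with total reads and 0.02 with DESeq2 size factors each bring it short of 2-fold. Hdc, the enzyme that makes histamine, was at -0.60. The median of the granule content list, -0.10, turned to 0.03 with total-read scaling. Nfil3 and Zfpm1 (-1.11), a GATA cofactor, fell among 27 mast cell transcription factors (median -0.21, percentile 16.4). The total-read shift of 0.13 brings Zfpm1 short of 2-fold. Pim2 fell (-1.61) among apoptosis regulators (median -0.16, percentile 22.1), and Dusp4, a MAP kinase phosphatase, fell (-1.37) among immediate early and NF-kB genes (median -0.30, percentile 10.03).

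Cytokines had a median log2 ratio of 0.20 (percentile 99.5) but a mean of -0.0040, which differs in sign. Of 12 measured, 2 rose, Il1b (2.36) and Csf2 (1.22), both at low counts in WT (17 and 25 reads) and each found in 1 WT single cell. All 11 measured chemokines lay above 0 (median 0.39, percentile 99.1), of which Ccl6 (2.02), found in no WT single cell, and Cxcl2 (1.18), found in 1, passed. Summed macrophage markers rare in MMC9s were 3.03-fold higher in the same library (2.68 to 3.44). Unfolded protein response genes lay at 0.23 (percentile 100, none past the rule), as in Hsp90b1 (0.75). Housekeeping genes lay at 0.10 (percentile 99.6) with members on both sides, Actb at 0.60 and Gapdh, which fell, at -1.35. Abundant genes as a whole lay below 0 in this comparison. The median log2 ratio was -0.24 over genes with 1000 reads or more in the larger library and -0.14 over those with 200 to 1000. Lists are placed among genes of like level, so a list of abundant genes can stand apart with a median near 0.

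Proliferation genes had a median of 0.66 (percentile 100), with 32 of 33 above 0 and 6 past the rule. Uhrf1 (2.15), Mcm7 (1.91), Kif11 (1.47), Mcm6 (1.34) and Top2a (1.12) were among the 6, and Mki67 reached 0.89. Macrophage or monocyte markers had a median of 1.70 (percentile 100), with 8 of 14 past the rule, among them the complement gene C1qa (2.19), Csf1r (1.96), the mannose receptor Mrc1 (1.95) and Lyz2 (1.85). Dendritic cell markers, largely MHC class II genes, had a median of 1.38 (percentile 100), with 4 of 6 past the rule, such as H2-Aa (1.42), H2-Eb1 (1.40) and the invariant chain Cd74. B cell or plasma cell markers had a median of 1.09 (percentile 100), with 4 of 11 past the rule, including Ighg1 (1.56), Ighm (1.42), Jchain (1.22) and Igkc (1.17). Epithelial markers had a median of 3.09 over 13 measured genes (percentile 100), with zeros at the floor and 53 reads in WT against 346 in IL4Ra-/- over the 22 list genes rare in MMC9s. Lgals4 (1.33) alone passed there, while Anpep, the aminopeptidase also read in 42.5% of WT cells, was at -0.65. The 4 measured ILC2 markers lay at -0.93 (percentile 0.040), where Il2ra fell (-1.25), whereas the 8 ILC2 list genes rare in MMC9s were 2.37-fold higher in sum (1.37 to 4.25, from 19 to 50 reads).

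Among the 8 highest genes of IL4Ra-/- were also the immunoglobulin segment Igkv8-24 (5.46), the macrophage gene Mpeg1 (2.09), Igkv1-110 (1.998), H19 (1.67) and H2-Ea-ps (1.59), an MHC class II gene annotated as a pseudogene. The 8 lowest included Dyrk3 (-1.32), Tbc1d10a (-1.28), Fau (-1.27), which encodes a ribosomal protein fused to a ubiquitin-like one, and Serpina3g (-1.22). Lists not apart were mast cell markers (-0.11), surface receptors (-0.009), interferon response (-0.002) and glycolysis (-0.11), which all turned positive with total-read scaling. IL-4 and STAT6 induced genes (-0.35, percentile 2.73), eicosanoid synthesis (-0.17), oxidative phosphorylation (-0.14), cell stress (-0.27), basophil (-0.19), T cell (0.77), cytotoxic lymphocyte (0.68), stromal or endothelial (-0.15) and progenitor markers (-0.19) were not apart.

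**Figure D2:**
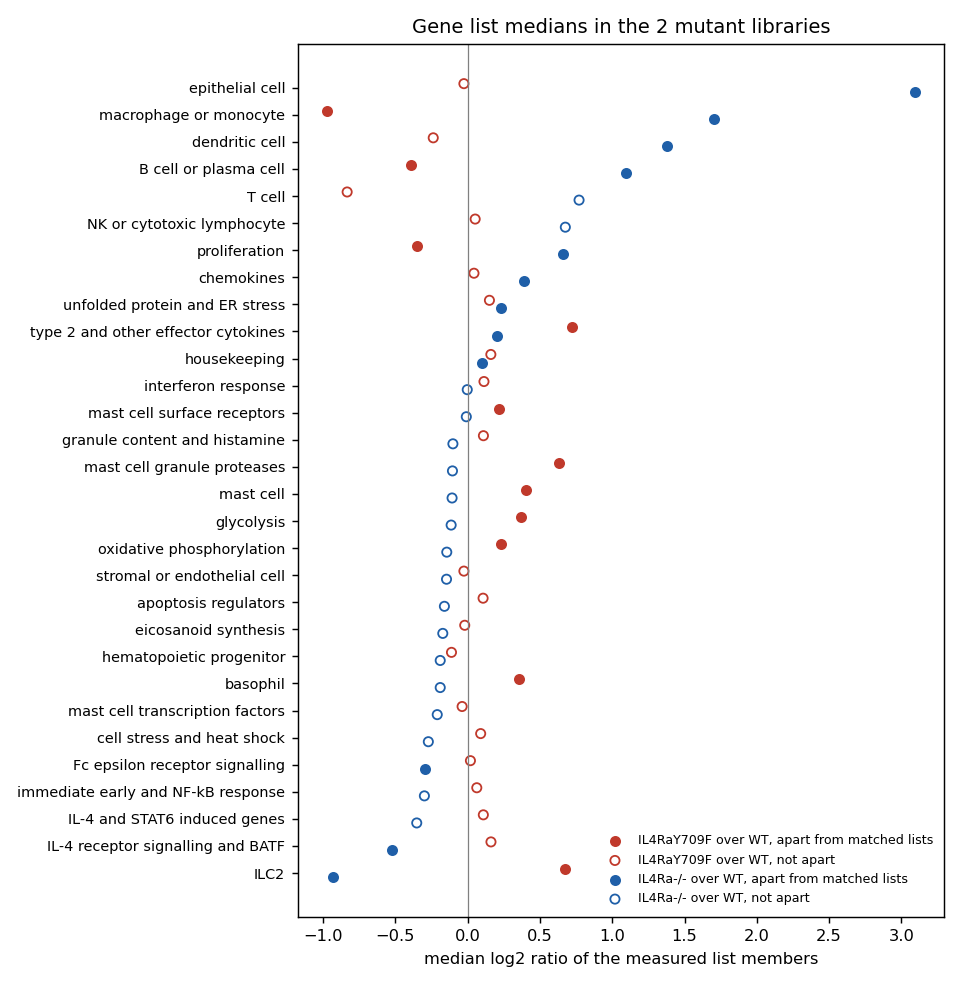
Median log2 ratio against WT (x axis) of the measured members of each gene list (y axis) in IL4RaY709F (red) and IL4Ra-/- (blue); filled points lie in the outer 5% of 10000 matched random lists, open points do not. Macrophage and proliferation lists are filled on opposite sides of 0 in the 2 mutants, and granule proteases are filled in IL4RaY709F only.

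Setting the mutants against each other asked which genes lie in the order of receptor activity. Between IL4RaY709F and IL4Ra-/-, 292 genes were higher and 221 lower of 6319, and total-read scaling, which shifts these ratios by -0.24 log2, gave 145 and 359. Of the 221 lower genes 60 were immunoglobulin genes, and 54 were detected in no WT single cell. Of the 292 higher genes these were 0 and 7. Across 6097 protein-coding genes the ratio between the mutants had a Spearman rho of -0.30 with exon length. WT lay between the mutants for 447 of the 513 genes past the rule (87.1%), 261 rising and 186 falling with receptor activity. Such an order alone does not tell an effect of the receptor in MMC9s from transcripts of other cell types or a trend with gene length. Genes chosen for a difference between 2 libraries mostly have the other library between them. With the IL4Ra-/- ratios shuffled among genes, where 720.4 genes on average passed between the mutants, the share was 83.9% on average. It was at most 86.9% in 100 shuffles, just below the observed share. For unchanged libraries it depended on the spread, with 89.1% at a natural log SD of 0.138, where 42.1 genes passed between the mutants, and 73.6% (at most 77.2%) at 0.3, where 849 passed. The 8 largest rising genes with 200 reads or more were Serpina3f (log2 3.65 between the mutants), Pim2 (3.54), Socs1 (3.42), Serpina3g (3.34), Nfil3 (3.28), Prss34 (3.18), Batf (3.15) and Socs3 (3.06). Among the 8 largest falling genes were Lyz2 (-3.24), Mpeg1 (-3.02), Igkv1-110 (-2.31), Ighm (-2.29), Jchain (-2.26), Igkc (-2.20), Iglv1 (-2.16) and Igha (-2.09).

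Past the size rule in both steps were 14 rising genes, those 8 and Il2ra, Mt1, Ldlrad4, Rnf180, Bcl3 and Il4ra itself. Falling in both steps were 5 genes, Lyz2, Igkc, Jchain, Ighv3-6 and Igkv1-117. Mt1, Ldlrad4, Rnf180, Bcl3, Ighv3-6 and Igkv1-117 were named after their values were seen. With independent lists 0.93 and 0.29 genes would fall in these sets, and unchanged libraries with counting noise, under which few genes pass at all, gave 0 in both. With a spread of 0.3 (natural log SD) between unchanged libraries, at most 5 and 3 genes fell in these sets. The shared WT library moves both ratios the same way there, so such genes can hardly arise and these simulations do not decide. With shuffled ratios at most 4 and 5 genes fell in these sets, so the 14 rising genes lay above the shuffles and the 5 falling genes did not. In the shuffles 337 genes on average passed between IL4Ra-/- and WT, against 233 observed. Genes higher in both mutants numbered 4 (0.42 with independent lists, 0.04 simulated), namely H19, Fkbp1a, Akr1c13 and Igkv14-111, the last 3 named after their values were seen, and genes lower in both numbered 9 (0.64 and 0.02). Since both ratios share the WT library, unchanged libraries gave 2.85 and 1.71 such genes on average (at most 7 and 5) with a spread of 0.138, and 109.4 and 112.5 with a spread of 0.3. Across 5264 genes the 2 ratios had a Pearson r of 0.08 and a Spearman rho of 0.12, against a Pearson r of 0.51 for unchanged libraries. Their covariance was 0.0087 against 0.014 simulated, a difference of -0.0055. With WT reads thinned into 2 parts r was -0.04. Genes are not independent replicates, so no test was made.

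**Figure D3:**
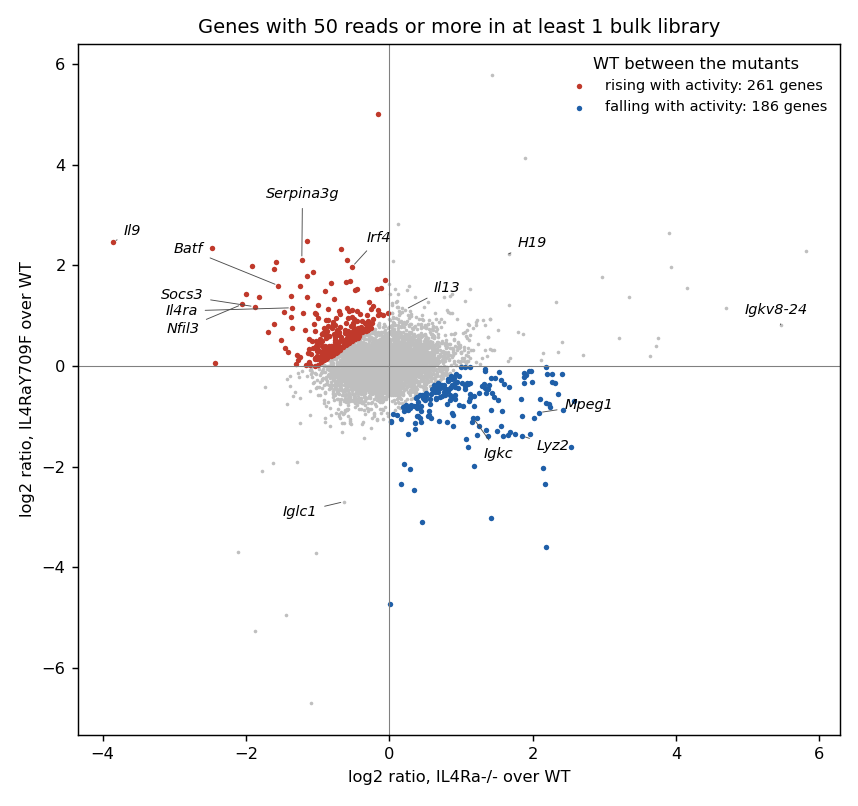
Log2 ratio to WT of each gene with 50 reads or more in at least 1 library, in IL4Ra-/- (x axis) and IL4RaY709F (y axis); zeros are drawn at the floor of 3 reads. Red marks the 261 genes and blue the 186 genes with WT between the mutants and past the size rule between them, in rising and falling order of receptor activity.

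The single-cell data asked which transcripts individual WT MMC9s carry. Mast cell transcripts passed the detection limit in nearly all cells, whereas Il4, Il6 and Il13 passed it in a part of the cells, Il9 passed it in 1 cell, and 4 of the 17 genes of the cytokine list passed it in none. At 10 reads or more, Cpa3, Mcpt1 and the IgE receptor chain Fcer1a were found in all 80 cells kept (95.5% to 100%), Kit in 98.8% (93.2% to 100%) and Mcpt2 in 95% (87.7% to 98.6%). The limit is low for such abundant transcripts: a pair of cells with 48.1% and 73.2% immunoglobulin reads passed it with 98 and 76 reads of Cpa3, against a median of 21595 in the other 78, and 65 of the 80 cells held at least 100 CPM of both Cpa3 and Mcpt1. Il4, which the sort selected through its GFP reporter, was found in 71.2% of cells (60.04% to 80.8%), Il6 in 70% (58.7% to 79.7%) and Il13 in 15% (7.998% to 24.7%). Il9 passed in 1 cell, 1.25% (0.032% to 6.77%), which held 1137 of its 1139 reads.

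Among the factors of the receptor pathway, Batf was found in 63.8% of cells (52.2% to 74.2%), Stat6 in 55% (43.5% to 66.2%), Il4ra in 38.8% (28.1% to 50.3%) and Irf4 in 12.5% (6.16% to 21.8%). The highest mean CPM over cells belonged to mt-Rnr2, mt-Cytb, Actb, mt-Co1, mt-Nd1, Cpa3, Hdc, Mcpt1, Gm2a and Igha. By median CPM Actb (21921) and Cpa3 (16396) stood above mt-Rnr2, which had a mean of 29944 and a median of 13664, and mt-Cytb (mean 26809, median 10707). The Igha mean came from a pair of cells that held 99.7% of its reads. Of the 14 mast cell markers 13 were found in at least 50% of cells. Immediate early and NF-kB genes were also common, with 18 of 29 in at least 50% of cells, such as Egr1 and Cd69 in 98.8% each. What raised them was not tested. Chemokine transcripts were frequent for Ccl2 and Ccl4 (85.0% each) and Ccl3 (56.2%), while 10 of 22 chemokines were found in no cell. Proliferation genes reached up to 46.2% (Hmgb2), with Pcna in 43.8%.

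Markers of other cell types ranged from undetected to common. No eosinophil, neutrophil or erythroid marker was found in 5% of cells, and 16 of 24 epithelial, 11 of 13 stromal or endothelial and 11 of 12 neutrophil markers were found in no cell, which has an exact upper limit of 4.51% each. In other lists single markers were frequent. These included Cx3cr1 (85.0%) of the macrophage list, Pecam1 (56.2%) of the endothelial list and Xbp1 (47.5%) of the B cell or plasma cell list. Anpep (42.5%) of the epithelial list, Cd3e (37.5%) of the T cell list, H2-Ab1 (27.5%) of the dendritic cell list and Il7r (23.8%) of the ILC2 list were others. Igha passed the limit in 33.8% of cells, but 99.7% of its reads lay in 2 cells. The other 78 cells had a median of 4 Igha reads, and 25 of them passed. In at least 5% of cells were 7 of 14 B cell or plasma cell, 4 of 11 progenitor and 9 of 11 basophil markers, the last including genes that mast cells share, such as Fcer1a. Summed over the kept cells, expression correlated across 13099 genes with WT bulk (Spearman 0.763, Pearson 0.778 on log2(CPM + 1)). The libraries came from different mouse models and protocols, and genes are not independent, so single levels were not compared between them.

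**Figure D4:**
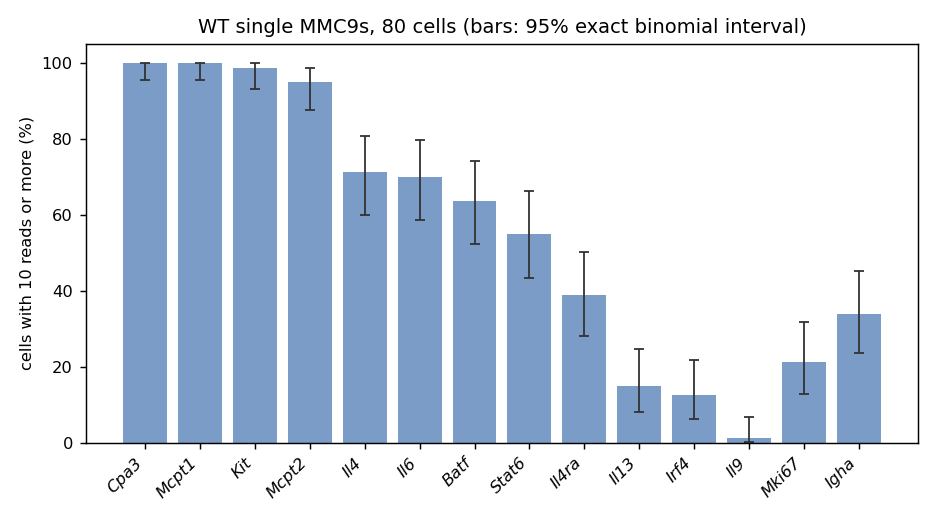
Share of the 80 WT single MMC9s with 10 reads or more (y axis, percent) for 14 genes (x axis), with exact 95% binomial intervals. Mast cell transcripts stand near 100%, Il4 and Il6 near 70%, and Il9 at 1.25%.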

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

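All tests of technical and biological explanations given here, and their thresholds, were chosen after the results were seen.

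The single cell left out of the shares, with 1225 gene reads and 680 detected genes, still held reads of 4 of the always-named genes above the limit that a count of 0 allows (3 reads). These were Mcpt1 with 12 reads, Cpa3 with 12, Mcpt2 with 5 and Il6 with 5. It also held 30 reads of Hdc, 1 of Il4 and 0 of Il9.

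Transcripts of macrophages, dendritic, epithelial and plasma cells were higher in the IL4Ra-/- library. Library scaling as the cause is argued against by the place of the macrophage list among matched lists (percentile 100). That place does not move with 1 factor for all genes. The lowest median log2 ratio of the list over 4 scalings was 1.70. The other scalings move ratios to WT by at most 0.135 log2 in size, so this median could not come near 0 and does not decide. A lower share of mast cells would raise all other cell types alike. Of 13 types, 8 had summed markers outside the pooled fold of 2.23 (2.07 to 2.41), 2 above and 6 below. Of the 6, basophil markers (2 genes, 124 reads in WT) lay at 0.638 of WT (0.480 to 0.845). Eosinophil markers (108 reads in WT, 98 of them Siglecf) lay at 0.749 (0.560 to 0.999974). A rise of all other types alike is argued against by these sums, if their reads came from such cells, which was not tested. The rest of the 6 do not decide, since sums of few reads (13 in WT for erythroid markers) need not follow that share. The 2 types above the pooled fold were macrophage (3.03, 2.68 to 3.44) and epithelial (5.87, 4.38 to 7.99). They rose unequally beyond counting error, which covers no spread between pools. More cells of some other types in the sorted IL4Ra-/- pool stay open as a source. Of the 152 higher genes, 30.9% (23.7% to 38.9%) had 10 reads in no WT single cell, and 10.7% (5.45% to 18.3%) without immunoglobulin genes. The share was 1.001% among genes that did not pass, matched to the 152 on the larger of the IL4Ra-/- and WT counts. Genes chosen as higher in IL4Ra-/- have lower WT counts than those. They are therefore less often detected in WT cells whatever the source, and the comparison does not decide. The single cells came from another model and were sorted as lineage-negative, a gate meant to remove cells of other types. Even so, a pair of the kept cells held 48.1% and 73.2% immunoglobulin reads and only 98 and 76 reads of Cpa3. Cells with few mast cell transcripts thus passed that gate. The bulk gate is not given in the sources used here. A change of the MMC9s themselves with genotype stays open and was not tested.

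Proliferation genes were higher in the IL4Ra-/- library. The list was lower in the IL4RaY709F library, with none of its members past the size rule and no call among members of at least 100 reads (-0.153, percentile 4.52). Scaling is argued against in IL4Ra-/-, because 1 factor for all genes does not move the place of the list among matched lists (percentile 100). Over 4 scalings the median log2 ratio stayed between 0.658 and 0.80 in IL4Ra-/- and between -0.45 and -0.35 in IL4RaY709F. The other scalings move ratios to WT by at most 0.135 log2 in size, so these medians could not change sign and do not decide. Cycling cells of other types in the IL4Ra-/- pool cannot be told apart from cycling MMC9s: all 17 WT single cells with Mki67 also held at least 100 CPM of Cpa3 and of Mcpt1, but cells of the IL4Ra-/- pool were not sequenced singly, and summed markers of 6 other cell types, ILC2 among them, were above WT there. An effect of genotype on division of MMC9s stays open and was not tested.

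The IL4Ra-/- library kept 39.03% of the WT level of Il4ra (34.3% to 44.3%). Unedited recipient cells in the sorted knockout pool could leave such reads. If recipient MMC9s with WT levels of all genes alone did, no gene would lie far below that share. The prediction does not cover recipient cells of other types. Outside immunoglobulin genes and pseudogenes, 1 gene had its counting interval below that of Il4ra, Nfil3 with 24.1% left (up to 32.9%), and Socs3 with 27.2% left (up to 34.8%) lay below the estimate of 39.03% but not below its interval. The pool with recipient MMC9s cannot be told apart from one without, since so few genes do not decide. Reads from a transcript of the targeted allele or from cells of other types, which also stay open, were not tested.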

How the results depend on the processing

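The counts restricted to genes detected in at least 2 WT single cells, the lists matched on exon length, and the shares without cells rich in immunoglobulin reads, were chosen after the results were seen; all other settings were fixed before the data were examined. No paired analysis was possible because each genotype had 1 library, which also leaves no library to leave out in turn. The log2 ratios of Il4ra, Batf, Il9, Il13 and Il4 against WT kept their sign and stayed within their counting interval. This held in all 40 combinations of gene, mutant and setting (3 other scalings and removal of 4 gene classes). Each scaling moves every ratio to WT by 1 constant, at most 0.135 log2 in size, so little change was possible. A further 461 combinations for single genes and lists were unchanged, where lists under a scaling were judged on sign alone. Beyond their narrow counting intervals, with the sign kept, moved 19 ratios of abundant genes such as Cpa3, Mcpt1 and Igkc.

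Counts of genes followed the size rule. With a read minimum of 10, 234 genes were higher and 213 lower in IL4RaY709F than in WT, 580 higher and 230 lower in IL4Ra-/- than in WT, and 518 higher and 796 lower between IL4RaY709F and IL4Ra-/-, with 1103 genes ordered with receptor activity. With a read minimum of 200 these were 43 and 8, 18 and 24, 145 and 29, and 164. With a 3-fold rule they were 29 and 13, 60 and 12, 72 and 104, and 151. Where the interval had to exclude a ratio of 2 they were 38 and 14, 62 and 19, 114 and 103, and 189. These settings change which genes can pass by their own construction. Without mitochondrial, ribosomal protein, hemoglobin and immunoglobulin genes, 29 genes were lower in IL4RaY709F. With total reads, 45 genes were lower in IL4Ra-/- than in WT, and 145 were higher and 359 lower between the mutants. Among genes detected in at least 2 WT cells, 87 were higher in IL4Ra-/- than in WT and 146 lower between the mutants.

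Matching random lists on exon length moved no list into or out of the outer 5%. List medians near 0 changed sign with scaling, by the shift that each scaling adds to all genes. With total reads the IL4Ra-/- medians became 0.031 for granule proteases, 0.034 for granule content, 0.126 for surface receptors, 0.133 for interferon response, 0.021 for glycolysis and 0.028 for mast cell markers. The IL4RaY709F medians became -0.088 for Fc epsilon receptor signalling, -0.044 for immediate early genes, -0.00031 for apoptosis regulators, -0.063 for chemokines, -0.017 for cell stress and -0.055 for cytotoxic lymphocyte markers. DESeq2 size factors gave 0.012 for surface receptors and 0.018 for interferon response in IL4Ra-/-, and upper quartiles -0.0021 for Fc epsilon receptor signalling in IL4RaY709F. The mean of cytokines in IL4Ra-/- was -0.0040, against a positive median, and the cause was not tested.

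The list of IL-4 receptor signalling and BATF in IL4RaY709F came to stand apart with no read minimum for members (0.197, percentile 98.2), with members of at least 100 reads (0.197, percentile 98.7) and with the mean of members (0.418, percentile 100), while proliferation genes in IL4RaY709F with at least 100 reads no longer stood apart (-0.153, percentile 4.52); the cause was not tested. The correlation of the fold changes was -0.030 with a read minimum of 200 and -0.040 with WT reads thinned into 2 parts.

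Depth set the shares of single cells. Counting cells with 1 read or more gave 33.8% for Il13, 85% for Il4 and 81.2% for Batf. Asking for 50 reads gave 2.5% for Il13, and thinning each cell to 50000 reads gave 0% for Il13, 31.2% for Il4 and 26.2% for Batf, so these shares count cells above a detection limit and not cells that express the gene.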

Other observations

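All values given here were chosen for mention after they were seen.

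The 1 single cell with Il9 held 1137 of its reads among 1528010 gene reads, and 2 further reads lay in the other cells. It was a mast cell by its transcripts, with 32858 reads of Cpa3, 4899 of Mcpt1 and 3609 of Kit, and it held 5786 reads of Il6, 36 of Il4ra, 12 of Il13 and 2 of Il4. Batf and Irf4 had 0 reads there. Across the 80 cells, Il4 and Il6 were found together in 46 cells, where independent detection would give 39.9, and Il6 and Il13 in 11 (8.4). The other pairs computed among Il4, Il6, Il13 and Batf also lay above independent detection, Il4 with Il13 in 10 (8.55), Il4 with Batf in 42 (36.3) and Il13 with Batf in 10 (7.65). Mki67 and Top2a, both markers of dividing cells, were found together in 11 cells, where independent detection would give 3.19. Mki67 and Igha lay below independent detection, in 3 cells (5.74). These numbers make no allowance for cells that differ in depth and quality, which raises joint detection by itself, so no association between genes is read from them. Lif, a cytokine of the IL-6 family, was found in 43.8% of cells and Tnf in 27.5%.

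A pair of the kept cells held 48.1% and 73.2% immunoglobulin reads. Their mast cell transcripts were low, with 112 and 29 reads of Mcpt1 and 98 and 76 of Cpa3, against medians of 4524.5 and 21595 in the other 78 cells. Those 78 cells had a median of 4 and at most 726 reads of Igha. In 11 cells over 20% of reads were mitochondrial, up to 90.8%, where the median over all kept cells was 5.003%.

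Ribosomal protein genes, 77 in number, had a median log2 ratio of 0.26 in IL4RaY709F and -0.49 in IL4Ra-/- against WT, and 0.71 between the mutants, where none of the 77 lay below 0. These are short genes, and over all protein-coding genes the log2 ratio had a Spearman rho with exon length of -0.24, 0.16 and -0.30 in these 3 comparisons. Markers rare in WT single cells were also summed per cell type. Macrophage markers were 3.03-fold higher in IL4Ra-/- than in WT (2.68 to 3.44, from 329 to 1111 reads), epithelial markers 5.87-fold (4.38 to 7.99), dendritic cell markers 2.60-fold (2.15 to 3.17), B cell or plasma cell markers 2.09-fold (1.47 to 3.02) and T cell markers 1.80-fold (1.14 to 2.89). Summed basophil markers lay at 0.638 of the WT level (0.480 to 0.845) and neutrophil markers at 1.06 (0.582 to 1.93). In IL4RaY709F, summed macrophage markers lay at 0.538 of the WT level (0.446 to 0.647) and stromal or endothelial markers at 0.520 (0.314 to 0.845), and the intervals of the other sums in that library included 1.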
